A study of Mus musculus with 21 samples.

How the data were processed

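The files used were gene abundance tables, 1 per library, with the columns coverage, FPKM and TPM. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 and levels were estimated with StringTie, and the versions and parameters of both tools are not given in the sources used here. The coverage values (signal) are the mean read depth per base of a gene, as deposited per the file headers. The FPKM values were scaled for gene length and library size before they were deposited, per the file headers. The TPM values were scaled by the authors in the same tables so that each library has the same sum, per the file headers. No read counts were used, so tests that need counts were not run. Strand is not stated, so levels of overlapping or antisense genes are uncertain.

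Per the labels, polyadenylated RNA was extracted with Trizol and sequenced as paired ends on an Illumina HiSeq, Illumina NovaSeq or MGI2000 instrument, and the labels do not say which library ran on which. ESCs grew on gelatin with serum, LIF, 1 µM PD0325901 and 3 µM CHIR99021. The treatment text names removal of LIF and 2i or addition of 2 µM RA for 12 h and 24 h. The labels name no knockout clone and no cell line beyond ESC. Groups of 3 libraries were taken from the sample titles, and the titles number the replicates without saying whether they were separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

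The time course tables list 32285 genes by Ensembl identifier, and the Cyp26a1 set tables list 25239 gene symbols without mitochondrial genes. Gapdh stood at 5786 to 7659 TPM in the time course and at 131 to 213 TPM in the Cyp26a1 set, so levels were never compared between the sets. Each set had its own model, and genes were matched by symbol where changes were set side by side. Depth was taken from the most frequent ratio of coverage to FPKM over genes, which gives aligned gigabases. That ratio was shared by 9.8% to 10.5% of genes in the time course and 55.7% to 56.5% in the Cyp26a1 set. Pearson r of log2(TPM + 1) within groups was 0.958 to 0.996 in the time course and 0.975 to 0.995 in the Cyp26a1 set.

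Before the data were examined, the groups, 6 comparisons, 22 gene lists, thresholds and a first set of other settings were fixed. The comparisons were noRA_12h and noRA_24h against ESC_0h, RA_12h against noRA_12h, RA_24h against noRA_24h, the change of the RA effect between these times, and knockout against wild type. Genes with at least 1 TPM in at least 3 libraries of a set were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend). All 15 time course libraries were fitted in 1 model and the 6 Cyp26a1 set libraries in another. Calls were made at a Benjamini-Hochberg adjusted p below 0.05. A pseudocount of 1 makes changes of low genes smaller than their TPM ratios. Genes listed at 0 in a whole group were given as levels in comparisons with that group, except for the change of the RA effect of Hoxb8, which is printed with a note.

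Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, and as an alternative with the correlation estimated from the residuals. Members were also adjusted over the list alone. Clustering along chromosomes counted neighbouring tested genes that were both higher, against 10000 shuffles of gene order. Genes higher or lower with RA were tested as sets in the knockout comparison with camera. Exonic length and GC content came from GENCODE M21, which matched 99.92% of the genes tested in the time course and 98.01% of those in the Cyp26a1 set. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

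Named genes followed a rule. For the RA and knockout comparisons these were the 8 highest and 8 lowest genes past the threshold whose libraries did not overlap between groups, for the other comparisons the 5 highest and 5 lowest. Predicted gene models were left out, and some genes that meet the rule are not reported here. Added to these were up to 4 members per list, mostly those with the largest change, preferring calls that held without each library in turn. Cyp26a1 and the genes that start within 1 Mb of it were always looked up.

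That first set of other settings was a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, FPKM, eBayes without a trend, replicate number as a block, leaving out each library in turn, and a model of only the groups compared. For the RA genes in the knockout these were the genes called at 12 h, 2-fold changes only, an estimated correlation and the block, and for clustering the 4 Hox clusters left out and 2-fold changes only. Chosen after the data were seen were a correction for GC content and length (natural splines with 4 degrees of freedom per library), a covariate for the axis on which libraries of a group differ, and the joint removal of noRA_12h library 1 and RA_24h library 2. Also added then were the list tests under other scalings or without single libraries, the RA targets without Cyp26a1, and clustering without overlapping pairs. No library was left out of the tests reported as main results.

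Replicate numbers were checked as possible pairs. In the Cyp26a1 set the 3 pairs of wild type and knockout libraries with the same number had correlations of 0.19, 0.32 and 0.54 after group means were removed. All were above 0.1, but so were 2 of 6 pairs with different numbers, at 0.27 and 0.23. The block alternative thus has only a weak basis there. The scripts were run on simulated values with known changes. Of genes with a true log2 change of 0.5, 34.3% to 58.2% were called in comparisons of 2 groups and 16.4% to 23.9% for the change of the RA effect, so smaller changes are often missed. Of the unchanged genes 0 to 12 were called in each run. Where the axis on which libraries of a group differ was added, its scores averaged 0 within each group. Those runs could therefore not show false calls from an axis that shifts a whole group. Of 50 unchanged lists 0 were called, but only with independent noise, so false list calls among correlated genes were not tested. Transcript-level values, coverage as a measure of expression, and mitochondrial genes in the knockout comparison were not analysed here.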

Results

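Polyadenylated RNA was sequenced from 21 libraries of mouse embryonic stem cells (ESCs), in 7 groups of 3. In the time course, wild type ESCs grown with serum, LIF and the inhibitors PD0325901 and CHIR99021 (together called 2i) were taken at 0 h (ESC_0h). Others were taken after 12 h and 24 h without LIF and 2i (noRA_12h and noRA_24h) or after 12 h and 24 h with 2 µM retinoic acid (RA_12h and RA_24h). The labels do not say whether LIF and 2i were also removed from the time course cells that received RA. In RA_12h Dusp6, Socs3 and Sp5, which answer to ERK, LIF and WNT signalling, stood at 133, 12.9 and 0.138 TPM. They stood at 76.1, 8.42 and 0.161 TPM in noRA_12h and at 4.51, 159 and 49.2 TPM in ESC_0h. These genes, looked up for this question after their values were seen, were thus nearer to the level without LIF and 2i, while Otx2 (17.6 TPM) lay between 3.76 and 86.9 TPM. A separate set held wild type and Cyp26a1 knockout ESCs, each given 2 µM RA for 24 h after LIF and 2i were removed. Aligned sequence came to 2.96 to 3.91 gigabases per library in the time course and 2.72 to 3.24 in the Cyp26a1 set. Between 11928 and 13482 genes per library reached 1 TPM, and the 10 most abundant genes held 4.88% to 6.22% of all TPM. Values below are mean TPM ± SD with n = 3 libraries per group, and changes are differences of log2(TPM + 1) with their standard error (SE).

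Cyp26a1 (ENSMUSG00000024987), which encodes an enzyme that breaks down retinoic acid, lies on chromosome 19 from 37697798 to 37701536 in mm10. It was listed at 0 in all 3 ESC_0h libraries and, without RA, at 0.472 ± 0.287 TPM at 12 h and 0.750 ± 0.186 TPM at 24 h. A listed 0 need not mean absence in these values, as the housekeeping gene Hprt was also listed at 0 in part of the time course libraries. With RA it reached 121 ± 1.70 TPM at 12 h and 313 ± 28.7 TPM at 24 h. In the Cyp26a1 set it stood at 595 ± 10.8 TPM in the wild type and 4.52 ± 0.458 TPM in the knockout, which is 0.761% of the wild type mean and 131-fold lower. Every knockout library (4.03 to 4.93 TPM) lay below every wild type library (585 to 606 TPM), so the genotype labels and this gene go together in all 6 libraries.

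**Figure D1:**
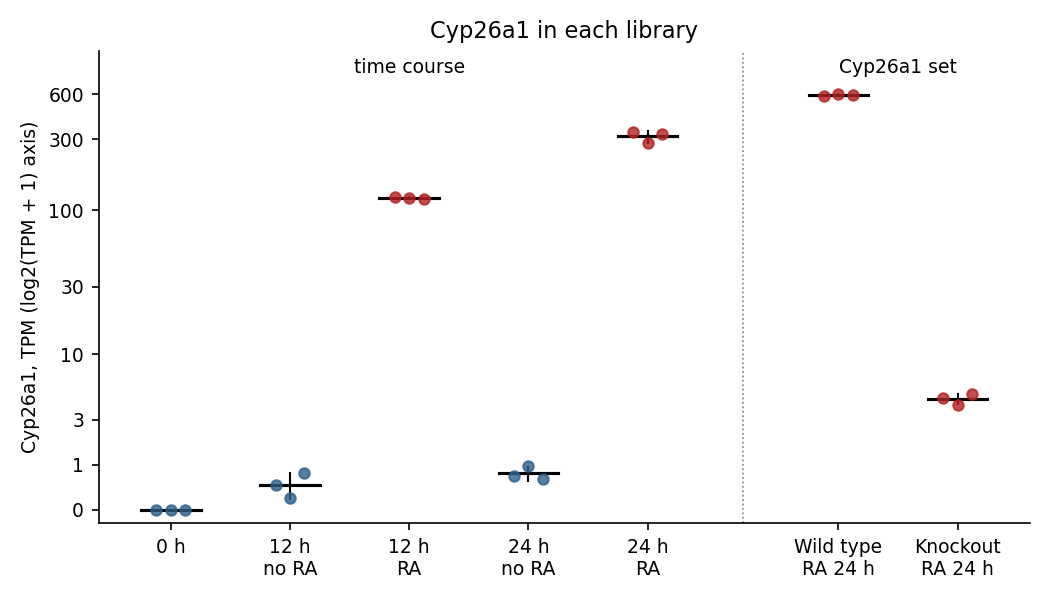
Cyp26a1 level in TPM on a log2(TPM + 1) axis for each of the 21 libraries (points), with the mean (bar) and SD (line) of each group. The gene lies between 119 and 122 TPM in the 3 RA_12h libraries, between 281 and 336 TPM in the 3 RA_24h libraries, and between 4.03 and 4.93 TPM in the 3 knockout libraries.

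The noRA groups compared with ESC_0h asked what changed after removal of LIF and 2i without RA. No group was kept in LIF and 2i for 12 h or 24 h, so removal cannot be told from time in culture. After 12 h Otx2, a transcription factor of the formative and primed states, went from 3.76 ± 0.414 to 86.9 ± 6.89 TPM and rose by 4.21 (SE 0.10). Socs3, which STAT3 induces downstream of LIF, fell by 4.10 (SE 0.14), from 159 ± 8.10 to 8.42 ± 1.59 TPM. Sp5, a WNT-responsive transcription factor, fell by 5.43 (SE 0.14), from 49.2 ± 6.53 to 0.161 ± 0.167 TPM. Dusp6 and Spry4, both feedback regulators induced by ERK signalling, rose by 3.81 (SE 0.09) and 3.81 (SE 0.07). Among the largest rises at 12 h were also Enox1 (4.92, SE 0.24), S100a6 (4.60, SE 0.13), Myrf (4.39, SE 0.09), Enpp3 (4.33, SE 0.13) and Lgals3 (4.27, SE 0.09). Among the largest falls were also Tnni1 (-4.87, SE 0.20), Trpm1 (-4.74, SE 0.14) and Nkx1-2 (-4.05, SE 0.14). The highest adjusted p among these genes was 3.06e-09, for Enox1.

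At 24 h without RA the rise of Otx2 measured 5.15 (SE 0.10), to 168 ± 5.65 TPM, and Pou3f1, another formative transcription factor, rose by 4.90 (SE 0.13). Enpp3, Enox1 and Car4, a carbonic anhydrase, rose by 5.61 (SE 0.13), 5.36 (SE 0.24) and 5.09 (SE 0.10). Among the largest falls were those of Trpm1 (-6.49, SE 0.14), Sp5 (-5.55, SE 0.14), Pglyrp1 (-5.18, SE 0.14) and Tlx2 (-4.72, SE 0.16). Cdx1, a homeobox gene that both WNT and RA induce, was also among them and fell by 5.27 (SE 0.12), from 64.5 ± 4.41 to 0.691 ± 0.0443 TPM. Of 13948 genes tested, 3073 were higher and 2849 lower at 12 h, and 3547 were higher and 3697 lower at 24 h. At 24 h 1137 of the higher and 883 of the lower genes changed by 2-fold or more.

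Gene lists fixed in advance moved with these genes. The formative and primed pluripotency list had 15 members higher, 0 lower and 1 not past the threshold at both times (15 higher when adjusted over the list alone, camera adjusted p = 4.59e-13 at 12 h and 5.93e-13 at 24 h). Of the naive pluripotency list 13 members fell at 24 h, 1 rose and 1 was not past (13 lower and 1 higher adjusted over the list alone, adjusted p = 2.97e-07). Tfcp2l1, Klf4 and Esrrb, factors of the naive network, fell by 3.25 (SE 0.10), 2.70 (SE 0.07) and 2.26 (SE 0.10), while Nr0b1 of the same list rose by 2.32 (SE 0.10). In the general pluripotency list 8 members rose at 24 h, 0 fell and 4 were not past (8 and 0 adjusted over the list alone, adjusted p = 4.67e-04), among them Utf1 (3.62, SE 0.10) and Dppa2 (3.17, SE 0.12). LIF and STAT3 targets had 1 higher, 8 lower and 3 not past at both times (the same counts adjusted over the list alone, adjusted p = 4.79e-04 and 3.04e-04). WNT and beta-catenin targets had 2 higher, 10 lower and 1 not past at both times (the same counts adjusted over the list alone, adjusted p = 5.05e-04 and 0.00168). ERK pathway targets had 11 higher, 0 lower and 3 not past at 24 h (11 and 0 adjusted over the list alone, adjusted p = 2.97e-07). Of the Hoxc and Hoxd clusters 8 members fell, 0 rose and 1 was not past at both times (8 lower adjusted over the list alone, adjusted p = 4.79e-04 and 6.06e-05), such as Hoxc12, which fell by 3.08 (SE 0.16) at 24 h. These 7 lists also passed at 24 h with an estimated correlation.

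Other lists passed only with the preset correlation. At 24 h germline and meiosis had 7 higher, 1 lower and 4 not past (7 and 1 adjusted over the list alone, adjusted p = 0.0388, or adjusted p = 0.298 with an estimated correlation), with Mael rising by 3.51 (SE 0.09). DNA methylation machinery had 5 higher, 1 lower and 3 not past at 24 h (5 and 1 adjusted over the list alone, adjusted p = 0.0342, or adjusted p = 0.178 with an estimated correlation). Dnmt3a and Dnmt3b, which set new methylation marks, rose by 4.09 (SE 0.08) and 2.38 (SE 0.06). Dnmt3l of the same list rose by 3.28 (SE 0.07), while Uhrf1, a maintenance factor, fell by 0.46 (SE 0.08). The trophoblast list had 3 higher, 6 lower and 1 not past at 24 h (3 and 6 adjusted over the list alone, adjusted p = 0.0452, or adjusted p = 0.197 with an estimated correlation). Its call ended without noRA_24h library 3 (adjusted p = 0.0578) and after correction for GC content and length (adjusted p = 0.106). At 12 h ERK pathway targets (10 higher, 2 lower, 2 not past, adjusted p = 1.37e-05, or adjusted p = 0.0713 with an estimated correlation), naive pluripotency (2, 9 and 4, adjusted p = 0.0144, or adjusted p = 0.110 with an estimated correlation) and p53 and stress response (3, 7 and 5, adjusted p = 0.0194, or adjusted p = 0.110 with an estimated correlation) passed in the same limited way. Their counts adjusted over the list alone were 10 and 2, 2 and 9, and 3 and 7.

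The RA_12h libraries compared with noRA_12h asked what RA added after 12 h. Stra8, a gene named for its induction by RA and needed for entry into meiosis, went from 7.65 ± 1.31 to 301 ± 8.86 TPM and rose by 5.13 (SE 0.11). Hoxa5, a patterning gene of the Hoxa cluster, rose by 4.50 (SE 0.12), to 24.6 ± 0.791 TPM. Cdx1, an upstream regulator of Hox genes, went from 3.66 ± 0.768 to 104 ± 4.26 TPM, and Stra6, the cell surface transporter of retinol, from 0.859 ± 0.187 to 26.4 ± 0.818 TPM. Otx2 fell by 2.24 (SE 0.10), from 86.9 ± 6.89 to 17.6 ± 2.02 TPM, and Grhl2, an epithelial transcription factor, fell by 2.16 (SE 0.11), from 22.5 ± 0.989 to 4.24 ± 0.162 TPM.

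Cyp26a1 had the highest change at 12 h, 6.39 (SE 0.13), and the 8 highest also held the fatty acid receptor gene Ffar3 (3.52, SE 0.21) and the water channel gene Aqp3 (3.50, SE 0.11). The lowest 8 held Lef1 (-1.80, SE 0.13), a mediator of WNT signalling, the imprinted RNA Meg3 (-1.80, SE 0.15), Glod5 (-1.95, SE 0.29) and Ly6g6e (-1.80, SE 0.20), with adjusted p from 6.39e-07 to 3.00e-04. Dst and Mdn1, both very long genes, were also among them (-2.04, SE 0.58, adjusted p = 0.0278, and -1.88, SE 0.60, adjusted p = 0.0455). Their levels differed widely within noRA_12h (15.8 ± 12.8 and 29.1 ± 24.0 TPM), and without noRA_12h library 1 the changes were -1.45 (adjusted p = 0.118) and -1.26 (adjusted p = 0.189). Both calls ended without each of the other compared libraries except noRA_12h library 2. In all, 1428 genes were higher and 1003 lower, 304 and 147 of them by 2-fold or more. A correction for GC content and length turned that split to 1611 higher and 2049 lower.

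By list, 12 of 18 retinoic acid targets rose at 12 h, 0 fell and 6 were not past (13 higher adjusted over the list alone, camera adjusted p = 2.90e-17). The Hoxa cluster had 9 higher, 0 lower and 1 not past (9 adjusted over the list alone, adjusted p = 1.50e-16), with Hoxa4 and Hoxa7 rising by 3.12 (SE 0.12) and 2.98 (SE 0.13). All 10 members of the Hoxb cluster rose (10 adjusted over the list alone, adjusted p = 1.17e-13), Hoxb4 by 2.22 (SE 0.12) and Hoxb2 by 2.02 (SE 0.14). Hoxb5, in the same cluster, was listed at 0 without RA and stood at 4.18 ± 0.683 TPM with it. These 3 lists were the ones that also passed with an estimated correlation (adjusted p = 9.11e-05, 2.07e-04 and 0.0231). Formative and primed pluripotency had 1 higher, 9 lower and 6 not past (2 and 9 adjusted over the list alone, adjusted p = 2.42e-04, or adjusted p = 0.0973 with an estimated correlation), with Foxd3 falling by 0.80 (SE 0.10). Endoderm had 5 higher, 2 lower and 10 not past (7 and 2 adjusted over the list alone, adjusted p = 0.0171, or adjusted p = 0.198 with an estimated correlation), led by the primitive endoderm factor Gata6 (3.36, SE 0.14). Primitive streak and mesoderm had 4 higher, 1 lower and 2 not past (4 and 1 adjusted over the list alone, adjusted p = 0.0323, or adjusted p = 0.116 with an estimated correlation). Wnt8a, T and Cdx2 rose by 1.69 (SE 0.17), 1.46 (SE 0.14) and 1.17 (SE 0.13), and Kdr fell by 1.24 (SE 0.12). Germline and meiosis had 4 higher, 0 lower and 8 not past (5 higher adjusted over the list alone, adjusted p = 0.0461, or adjusted p = 0.314 with an estimated correlation). The mesoderm call also ended after quantile normalization (adjusted p = 0.0573) and after correction for GC content and length (adjusted p = 0.0884), and the germline call without noRA_12h library 2 (adjusted p = 0.151).

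General pluripotency at 12 h had 1 higher, 3 lower and 8 not past (1 and 6 adjusted over the list alone, adjusted p = 0.0486, or adjusted p = 0.117 with an estimated correlation), and its call ended with median-of-ratios scaling (adjusted p = 0.115) and without noRA_12h library 3 (adjusted p = 0.0904). Dppa2, a chromatin factor of pluripotent cells, rose by 1.15 (SE 0.12), while Fgf4 and Sox2 fell by 0.87 (SE 0.08) and 0.45 (SE 0.06). DNA methylation machinery had 0 higher, 2 lower and 7 not past (4 lower adjusted over the list alone, adjusted p = 0.0138, or adjusted p = 0.117 with an estimated correlation), namely Dnmt3l and Dnmt3b, which fell by 0.78 (SE 0.07) and 0.62 (SE 0.06). The list of cohesin, CTCF, Mediator and looping factors had 0 higher, 1 lower and 14 not past (1 lower adjusted over the list alone, adjusted p = 0.00157, or adjusted p = 0.308 with an estimated correlation). Cohesin genes of the list had wide errors, such as Pds5a at -1.83 (SE 0.75). On the axis along which libraries of 1 group differed most, noRA_12h library 1 lay at 31.8, noRA_12h library 2 at -43.5 and the RA_12h libraries from -41.1 to -33.8.

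After 24 h of RA, against noRA_24h, the same questions were asked of the later response. Cyp26a1 rose by 7.49 (SE 0.13) and Stra8 by 5.71 (SE 0.11), to 822 ± 79.6 TPM. Hoxa5, Hoxa7 and Hoxb2 rose by 5.97 (SE 0.12), 4.87 (SE 0.13) and 5.09 (SE 0.14), to 78.9 ± 5.21, 52.2 ± 4.22 and 34.1 ± 7.25 TPM, while Hoxb5 was listed at 0 without RA and reached 35.7 ± 3.00 TPM. Cdx1 rose by 5.85 (SE 0.12), to 97.0 ± 11.3 TPM, and Zfp703, a transcriptional repressor, rose by 5.07 (SE 0.13). Fgf5, a marker of the primed state, fell by 3.60 (SE 0.14), from 13.7 ± 1.27 to 0.212 ± 0.0802 TPM, and Otx2 fell by 3.43 (SE 0.10), from 168 ± 5.65 to 14.7 ± 1.17 TPM.

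Of the lowest 8 at 24 h, the remaining members were Grhl2 (-3.40, SE 0.11), Vrtn (-3.40, SE 0.15), Enpp2 (-3.36, SE 0.16), the kinase gene Sgk1 (-3.34, SE 0.06), the proto-oncogene Mycn (-3.22, SE 0.09) and Lef1 (-3.20, SE 0.13), with adjusted p = 3.76e-09 or lower. In total 3178 genes were higher and 1737 lower, 605 and 436 of them by 2-fold or more. Without RA_24h library 2 the counts were 3861 and 3567, and after correction for GC content and length 2524 and 2981. That library lay at 51.6 on the axis named above, against -16.9 and -29.5 for the others of its group and 31.5, 23.2 and 39.0 for noRA_24h. Without it the RA_24h and noRA_24h libraries did not overlap on this axis. The larger counts then cannot be told from a difference along the axis.

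Retinoic acid targets had 16 higher, 0 lower and 2 not past at 24 h (16 adjusted over the list alone, camera adjusted p = 4.10e-16), among them Cyp26b1, a further RA-degrading enzyme, which went from 0.0468 ± 0.0810 to 21.3 ± 1.38 TPM. All 10 tested Hoxa and all 10 Hoxb members rose (10 and 10 adjusted over each list alone, adjusted p = 5.02e-15 and 2.14e-15). In the Hoxc and Hoxd clusters 6 rose, 0 fell and 3 were not past (6 adjusted over the list alone, adjusted p = 0.00485), Hoxc4 by 1.75 (SE 0.16). With FPKM in place of TPM the adjusted p of that list was 0.0849. Endoderm had 15 higher, 1 lower and 1 not past (16 and 1 adjusted over the list alone, adjusted p = 5.37e-12), with the endoderm transcription factors Gata6, Sox17 and Gata4 rising by 4.86 (SE 0.14), 3.92 (SE 0.26) and 3.69 (SE 0.16). Formative and primed pluripotency had 2 higher, 11 lower and 3 not past (3 and 11 adjusted over the list alone, adjusted p = 1.49e-06), and general pluripotency 0 higher, 6 lower and 6 not past (8 lower adjusted over the list alone, adjusted p = 6.61e-05), Fgf4 falling by 1.73 (SE 0.08) and Dppa4 by 0.77 (SE 0.10). These 7 lists passed with an estimated correlation too.

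**Figure D2:**
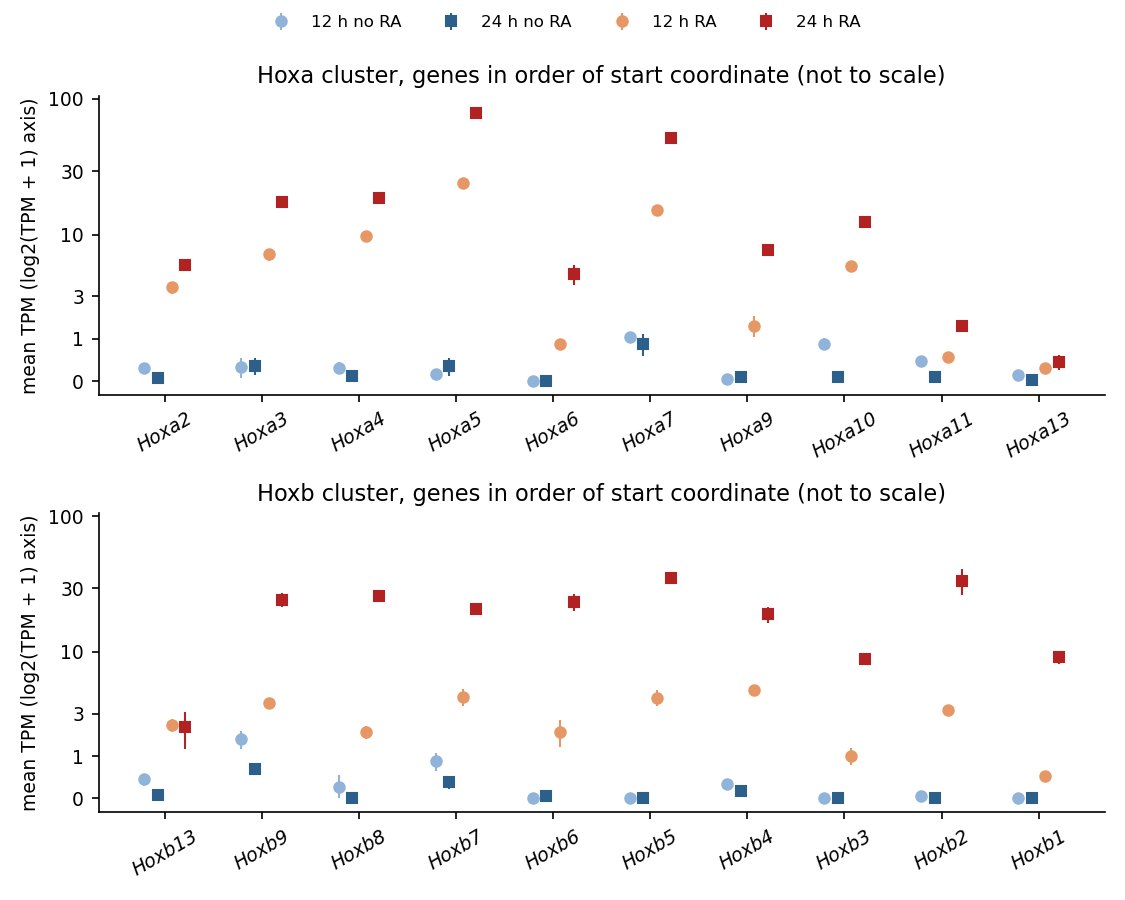
Mean TPM with SD (n = 3, log2(TPM + 1) axis) of genes of the Hoxa and Hoxb clusters in the order of their start coordinates, without and with RA at 12 h and 24 h. Hoxa5 lies at 24.6 TPM at 12 h and 78.9 TPM at 24 h with RA, and Hoxb5 at 4.18 and 35.7 TPM.

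Trophoblast markers had 7 higher, 0 lower and 3 not past at 24 h (8 adjusted over the list alone, adjusted p = 0.00413, or adjusted p = 0.0884 with an estimated correlation), with Tfap2c and the keratin gene Krt8 rising by 1.79 (SE 0.11) and 1.30 (SE 0.14). DNA methylation machinery had 0 higher, 4 lower and 5 not past (5 lower adjusted over the list alone, adjusted p = 0.00413, or adjusted p = 0.0676 with an estimated correlation), Dnmt3b falling by 1.45 (SE 0.06) and Dnmt3a by 0.72 (SE 0.08). The list of cohesin, CTCF, Mediator and looping factors had 0 higher, 2 lower and 13 not past (1 lower adjusted over the list alone, adjusted p = 0.0192, or adjusted p = 0.451 with an estimated correlation). Its call ended without RA_24h library 1 (adjusted p = 0.0511), without RA_24h library 3 (adjusted p = 0.0744) and after correction for GC content and length (adjusted p = 0.0754). The other lists did not pass as sets. Naive pluripotency had 5 higher, 9 lower and 1 not past (5 and 9 adjusted over the list alone, adjusted p = 0.139). Tbx3 rose by 2.27 (SE 0.06), while Tdh and Nr0b1 fell by 2.32 (SE 0.08) and 1.57 (SE 0.10). Retinoid synthesis and transport had 7 higher, 3 lower and 2 not past (7 and 3 adjusted over the list alone, adjusted p = 0.0867), with Rbp4, the retinol carrier of plasma, rising by 1.40 (SE 0.19).

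WNT and beta-catenin targets at 24 h had 4 higher, 3 lower and 6 not past (5 and 4 adjusted over the list alone, adjusted p = 0.876), with a mean of 0.26 while the median (-0.02) and the test pointed down. Dkk1, an inhibitor of WNT signalling, was listed at 0 without RA and stood at 3.99 ± 0.307 TPM with it, and the cyclin gene Ccnd1 fell by 2.05 (SE 0.08). Primitive streak and mesoderm had 5 higher, 1 lower and 1 not past (5 and 1 adjusted over the list alone, adjusted p = 0.0611), neural markers 2, 0 and 4 (2 and 0, adjusted p = 0.306), and LIF and STAT3 targets 5, 2 and 5 (5 and 3, adjusted p = 0.482). ERK pathway targets had 6 higher, 4 lower and 4 not past (6 and 4 adjusted over the list alone, adjusted p = 0.885), germline and meiosis 3, 1 and 8 (4 and 1, adjusted p = 0.373), and p53 and stress response 7, 1 and 7 (7 and 2, adjusted p = 0.215). Cell cycle genes had 0 higher, 3 lower and 12 not past (2 lower adjusted over the list alone, adjusted p = 0.120), and fibroblast (feeder) markers 2, 2 and 4 (2 and 2, adjusted p = 0.918, mean -0.06 and median 0.12). None of the 2-cell-like genes reached the minimum level for testing in the time course, so that list had 0 tested members there.

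**Figure D3:**
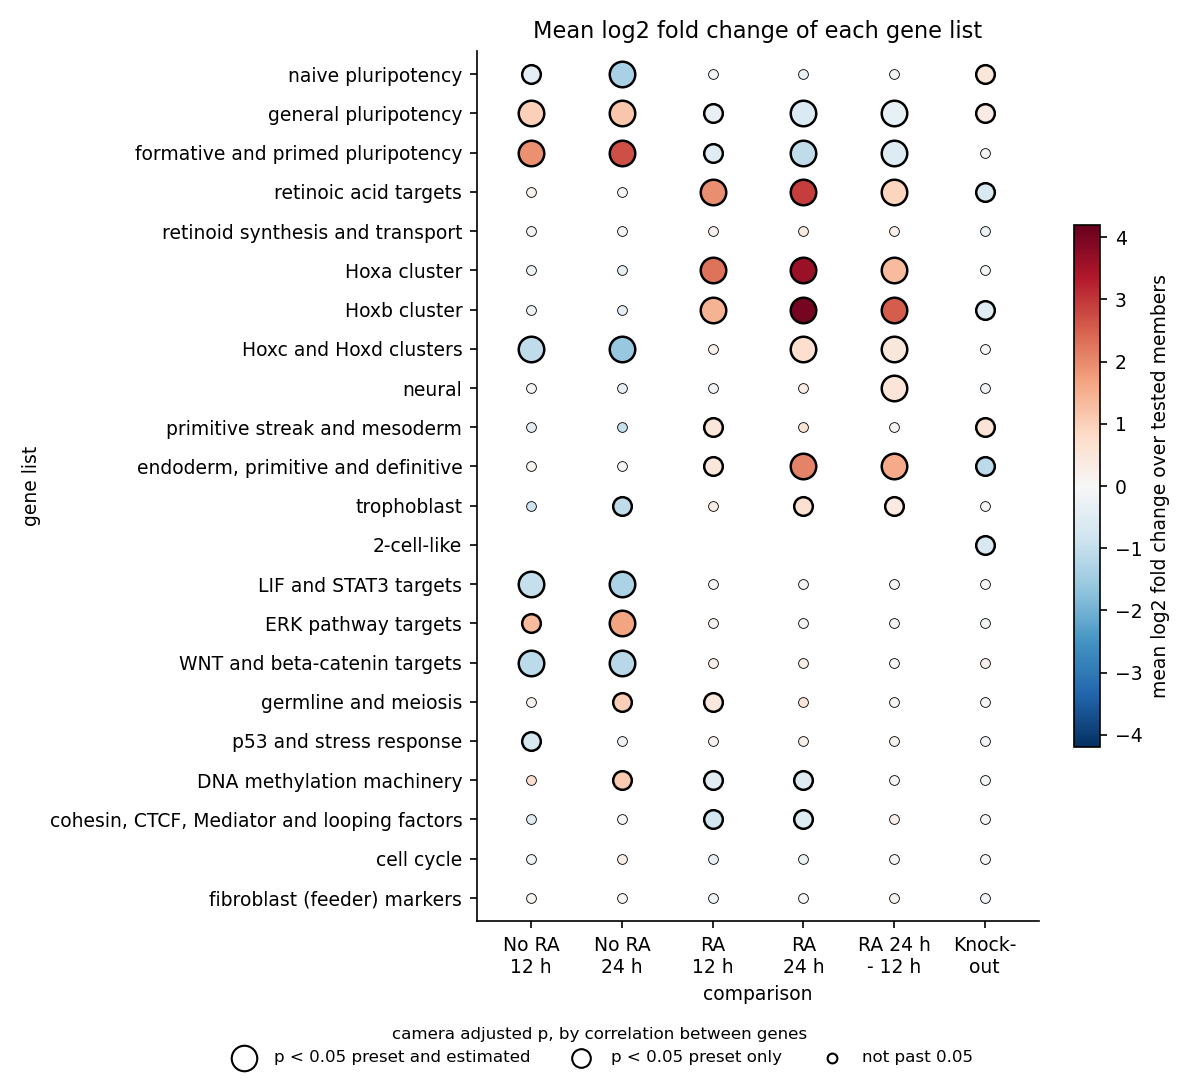
Mean log2 change of each gene list (lines) in each of the 6 comparisons (columns), coloured from lower (blue) to higher (red). The largest points passed camera with both the preset and the estimated correlation, middle points with the preset correlation only and the smallest with neither; the Hoxb cluster with RA at 24 h has the mean of largest size, 4.01.

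The change of the RA effect from 12 h to 24 h was tested as a difference of differences. Sox17 and Gata4, endoderm transcription factors, stood at 0.618 ± 0.592 and 0.996 ± 0.325 TPM with RA at 12 h and at 16.7 ± 2.54 and 15.7 ± 1.87 TPM at 24 h, and their RA effects grew by 3.60 (SE 0.36) and 3.23 (SE 0.22). Pgam2, a glycolytic enzyme of muscle, went from 5.61 to 89.4 TPM with RA (change of effect 3.84, SE 0.36). Hoxb9 went from 3.73 ± 0.0690 to 24.8 ± 3.09 TPM with RA (change of effect 3.14, SE 0.18), and Hoxb8, listed at 0 in noRA_24h, from 1.97 ± 0.318 to 26.5 ± 0.757 TPM. Enpp2, Vrtn and Fgf5 stayed under 1 TPM with RA and stood at 10.3 ± 1.64, 11.8 ± 0.704 and 13.7 ± 1.27 TPM in noRA_24h (changes of effect -2.93, SE 0.23, -2.91, SE 0.21, and -2.88, SE 0.20). Sgk1 fell with RA at both times, from 196 ± 6.64 to 91.9 ± 3.20 TPM at 12 h and from 162 ± 6.11 to 15.1 ± 0.976 TPM at 24 h (change of effect -2.26, SE 0.08), and Foxd3 had a change of effect of -2.16 (SE 0.15).

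The RA effect was higher at 24 h than at 12 h for 581 genes and lower for 374. Those counts were 1007 and 538 without RA_24h library 2, 333 and 311 without RA_24h library 1, 279 and 320 after quantile normalization, and 699 and 858 after correction for GC content and length. For Cyp26a1 the effect grew by 1.10 (SE 0.19, adjusted p = 0.00279), but with a pseudocount of 0.1 by 0.69 (adjusted p = 0.423). By list, the effect was higher at 24 h for 13 of 17 endoderm genes, lower for 0 and not past for 4 (14 higher adjusted over the list alone, adjusted p = 4.61e-20). The counts were 10, 0 and 0 for the Hoxa cluster (10, adjusted p = 4.41e-15), 9, 0 and 1 for the Hoxb cluster (9, adjusted p = 2.13e-23) and 12, 0 and 6 for retinoic acid targets (13, adjusted p = 5.61e-12). Hoxc and Hoxd clusters had 1, 0 and 8 (4, adjusted p = 0.0129) and neural markers 2, 0 and 4 (2, adjusted p = 0.00791), Sox1 growing by 1.31 (SE 0.17). Formative and primed pluripotency had 2, 8 and 6 (2 and 8, adjusted p = 1.54e-07) and general pluripotency 0, 4 and 8 (4, adjusted p = 2.48e-04). For Foxd3, Grhl2 and Fgf4 of these lists the lower effect was a stronger fall with RA, and for Dppa2 a smaller rise. Trophoblast had 3, 0 and 7 (5, adjusted p = 0.0283, or adjusted p = 0.203 with an estimated correlation), and the other 8 lists of this paragraph passed with an estimated correlation. After quantile normalization the calls of the Hoxc and Hoxd list and of trophoblast ended (adjusted p = 0.0722 and 0.131), as they did with FPKM (adjusted p = 0.0861 and 0.0711).

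Genes called at the first time were compared with those called at the second, in comparisons that share no control libraries. Of the 1428 genes higher at 12 h, 1147 were also called higher at 24 h, where 325 would be expected of independent lists, and 20 were called lower. Of the 1003 lower genes 676 were called lower again, with 125 expected, and 23 were called higher. Both comparisons used the same estimate of each gene's spread, so genes with a small spread are more readily called at both times. Part of the excess over independent lists can come from that. Because the series title speaks of clustered gene expression, neighbouring genes were counted along the chromosomes. At 12 h 330 pairs of neighbouring tested genes were both higher with RA, 2.26 times the mean of 146 in 10000 shuffles of gene order, and at 24 h 1104 pairs, 1.53 times the mean of 723 (one-sided permutation p = 1e-04 for both, the smallest these shuffles can give). Without the 4 Hox clusters the ratios were 2.16 and 1.51, among genes that changed by 2-fold or more 6.21 and 4.22, and among such genes without the Hox clusters 4.83 and 3.58. Neighbouring genes with related sequence or shared transcription are not independent, and the ratio was 2.19 and 1.52 when pairs of overlapping genes were left out.

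Around Cyp26a1 itself, 17 tested genes started within 1 Mb. Cyp26c1, an RA-degrading enzyme gene next to it, was listed at 0 without RA at both times and stood at 1.16 ± 0.259 TPM at 12 h and 2.53 ± 0.565 TPM at 24 h with RA. Fgfbp3, a binding protein of FGFs, rose by 0.53 (SE 0.13) and 0.98 (SE 0.13), and Myof, a membrane repair protein, fell by 1.01 (SE 0.14) and 0.87 (SE 0.14). At 24 h Rbp4, Plce1, Hhex and Ppp1r3c also rose, by 1.40 (SE 0.19), 1.27 (SE 0.23), 0.58 (SE 0.16) and 0.50 (SE 0.14). The calls of Fgfbp3 at 12 h (adjusted p = 0.0525 without RA_12h library 3), Hhex (0.0541 without noRA_24h library 2) and Ppp1r3c (0.0551 without noRA_24h library 1 and 0.0522 without noRA_24h library 3) ended without 1 library.

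The Cyp26a1 set asked how loss of this enzyme changed the transcriptome after 24 h of RA. Nanog, a core factor of naive pluripotency, was higher in the knockout, at 416 ± 4.95 against 167 ± 3.29 TPM (1.32, SE 0.04), and so were Nr0b1 (57.7 ± 6.62 against 22.5 ± 1.38 TPM) and the Nodal co-receptor gene Tdgf1 (296 ± 5.46 against 156 ± 2.17 TPM). Dab2, an endocytic adaptor of primitive endoderm, was lower, at 3.96 ± 0.376 against 18.7 ± 0.738 TPM (-1.99, SE 0.10). The endoderm factor Gata4 was lower as well, at 9.30 ± 0.826 against 31.0 ± 1.99 TPM. Stra8 stood at 780 ± 12.5 against 1258 ± 33.9 TPM (-0.69, SE 0.04) and Cyp26b1 at 16.5 ± 0.663 against 35.9 ± 1.62 TPM (-1.08, SE 0.07).

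Cyp26a1 was the lowest gene (-6.76, SE 0.07), and among the next were Dab2, the proteoglycan gene Srgn (-1.91, SE 0.07), Gpr50 (-1.81, SE 0.11), Ubash3b (-1.70, SE 0.13), the endocytic receptor gene Cubn (-1.68, SE 0.20) and S100g (-1.64, SE 0.18), which overlaps Ctps2. The highest were Ly6c1 (3.02, SE 0.15), Tmprss2 (2.07, SE 0.10), Ly6a (2.06, SE 0.10), Cpsf4l (1.71, SE 0.12), Ociad2 (1.66, SE 0.10), Otor (1.64, SE 0.27) and Msc (1.57, SE 0.15), and Akap2 was listed at 0 in the wild type against 4.80 ± 1.84 TPM. Ly6c1 and Ly6a belong to a family of similar genes and Akap2 overlaps Pakap, and reads shared with such neighbours cannot be told apart in these values. Otor lost its call without wild type library 1 (adjusted p = 0.0838) and without wild type library 3 (0.0748). In all, 429 of 12848 genes were higher and 855 lower, 57 and 107 of them by 2-fold or more. The 2-fold counts were 29 and 57 with FPKM. Median-of-ratios scaling gave 524 and 558, quantile normalization 395 and 477, and correction for GC content and length 933 and 868.

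Single libraries moved these counts widely. Without knockout library 3, which lay at 35.6 on the axis of differences within groups against -22.7 and -15.3 for the other knockout libraries, 982 genes were higher and 2178 lower. The wild type libraries lay at -5.88, -4.61 and 12.9, so without that library the groups did not overlap on this axis. Without wild type library 1, 2 or 3 the counts were 114 and 179, 120 and 205, and 115 and 186, and without knockout library 1 or 2 they were 207 and 470, and 137 and 373. With the preset correlation 7 lists passed camera, with all libraries as without each in turn, and with an estimated correlation 0.

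Endoderm had 0 members higher, 15 lower and 2 not past in the knockout (16 lower adjusted over the list alone, adjusted p = 2.53e-16, or adjusted p = 0.0586 with an estimated correlation). In the naive pluripotency list 7 were higher, 0 lower and 8 not past (7 and 1 adjusted over the list alone, adjusted p = 3.94e-07, or adjusted p = 0.0627 with an estimated correlation), and in general pluripotency 5, 0 and 7 (6 and 0, adjusted p = 4.63e-07, or adjusted p = 0.0586 with an estimated correlation), with Fgf4 at 0.76 (SE 0.07). The Hoxb cluster had 0 higher, 7 lower and 3 not past (9 lower adjusted over the list alone, adjusted p = 1.04e-06, or adjusted p = 0.0586 with an estimated correlation), Hoxb1 at -0.87 (SE 0.09) and Hoxb9 at -0.66 (SE 0.07). Retinoic acid targets had 2 higher, 8 lower and 8 not past (2 and 10 adjusted over the list alone, adjusted p = 1.29e-04, or adjusted p = 0.0586 with an estimated correlation). Without Cyp26a1 their mean was -0.32 (adjusted p = 0.00214, or adjusted p = 0.0771 with an estimated correlation). Primitive streak and mesoderm had 2 higher, 0 lower and 2 not past (2 adjusted over the list alone, adjusted p = 0.00102, or adjusted p = 0.0771 with an estimated correlation). Those were Kdr (1.07, SE 0.14), a receptor of vascular progenitors, and Wnt8a (0.55, SE 0.12). Without wild type library 1 their adjusted p was 0.0509 and 0.162, and the call of Wnt8a ended without each library but knockout library 3. The 2-cell-like list had 0 higher, 2 lower and 5 not past (5 lower adjusted over the list alone, adjusted p = 0.00560, or adjusted p = 0.415 with an estimated correlation), and its called members Zscan4b and Usp17lb, of families with near-identical copies, lost their calls without knockout library 1 (adjusted p = 0.0713 and 0.0539) and without knockout library 2 (adjusted p = 0.0912 and 0.107). Zscan4b also lost it without wild type library 1, 2 or 3 in turn (adjusted p = 0.0797, 0.117 and 0.119).

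Lists that did not pass in the knockout included the Hoxa cluster with 0 higher, 1 lower and 9 not past (1 adjusted over the list alone, adjusted p = 0.394), cohesin, CTCF, Mediator and looping factors with 0, 0 and 15 (0, adjusted p = 0.836) and WNT and beta-catenin targets with 3, 1 and 6 (3 and 1, adjusted p = 0.109). In the last list Dkk1 was lower (-1.42, SE 0.10), and Notum and Ccnd2 were higher (1.32, SE 0.16, and 1.30, SE 0.09). Aldh1a2, which makes RA from retinaldehyde, and Fabp5, a lipid carrier that can bind RA, were lower (-0.99, SE 0.12, and -1.14, SE 0.12), within a retinoid synthesis and transport list of 0, 3 and 7 (3 lower adjusted over the list alone, adjusted p = 0.255). Of 16 tested genes within 1 Mb of Cyp26a1, Slc35g1 was lower (-0.44, SE 0.09). Its call ended without 5 of the 6 libraries in turn, at adjusted p from 0.0660 without knockout library 1 to 0.122 without wild type library 3.

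The time course gave a list of RA-responsive genes that could be tested in these other libraries. Genes higher with RA at 24 h and tested in both sets had a median knockout change of -0.13 and a mean of -0.16, against -0.04 for other genes, and 472 of them were lower and 121 higher in the knockout (n = 2945 genes, camera p = 2.68e-05, not adjusted over the pair of sets). That p was 0.289 with an estimated correlation and 0.492 without knockout library 3. Without 1 library the counts ranged from 113 to 661 lower and from 38 to 242 higher. After correction for GC content and length they were 470 and 231. Among genes higher with RA at 24 h by 2-fold or more the median was -0.28 (n = 559 genes, camera p = 3.72e-08). Among the genes higher with RA at 12 h it was -0.06 (n = 1310 genes, camera p = 0.799). Genes lower with RA at 24 h had a median of 0.01 and a mean of 0.03, with 73 lower and 134 higher (n = 1440 genes, camera p = 1.55e-04, or p = 0.204 with an estimated correlation). Without 1 library 22 to 181 of them were lower and 38 to 226 higher. After correction for GC content and length their median was 0.09, with 74 lower and 264 higher. If the calls were independent, 197 genes would be expected to be higher with RA and lower in the knockout, and 47.8 to be lower with RA and higher in the knockout. Genes higher in both were also more than expected at 24 h, 121 against 97.8, while 73 against 96.2 were lower in both. For genes higher with RA at 12 h, 128 were higher in the knockout against 43.5 expected, and 198 lower against 87.5. Across 12112 genes, which are not independent replicates, the knockout change had r = -0.25 and rho = -0.20 with the RA effect at 24 h, and r = -0.09 and rho = -0.06 with that at 12 h.

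**Figure D4:**
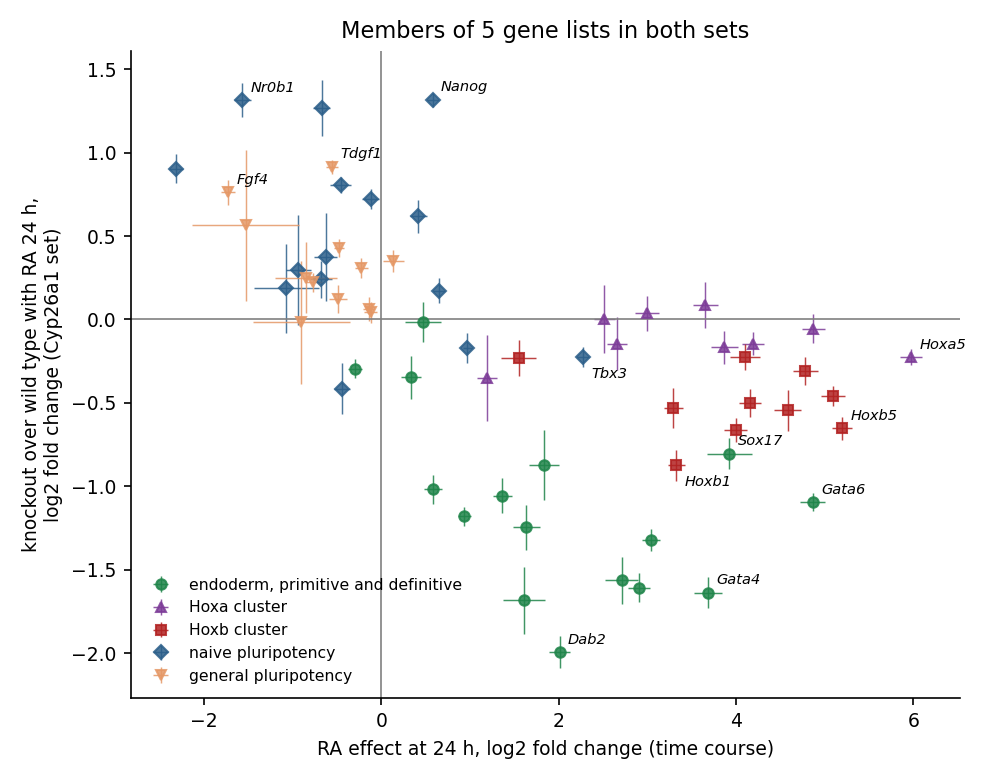
Log2 change with RA at 24 h in the time course (horizontal) and of the knockout over the wild type (vertical) for genes of 5 lists, as points with SE. Dab2 lies at 2.01 and -1.99, Gata4 at 3.69 and -1.64, and Nanog at 0.58 and 1.32.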

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

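The tests of GC content, the correction for GC content and length, the covariate for the axis within groups, the joint removal of libraries and the form of the test of other assignments of RA given here were chosen after the results below were seen, while those of sequencing depth and of developmental lists were written before.

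The RA effect was higher at 24 h than at 12 h for 581 genes and lower for 374, 955 in all. A rise of the effect need not be a rise of the gene, as Cdx1 (change of effect 1.35) stood at 104 TPM with RA at 12 h and at 97.0 TPM at 24 h. Among named genes the largest rises of the effect were Pgam2 at 3.84, Sox17 at 3.60, Hoxb8 at 3.45, Gata4 at 3.23 and Hoxb9 at 3.14. That of Hoxb8 involves a group listed at 0 (noRA_24h), so its size depends on the pseudocount. Among named genes the largest falls of the effect were Enpp2 at -2.93, Vrtn at -2.91, Fgf5 at -2.88, Sgk1 at -2.26 and Foxd3 at -2.16. For Cyp26a1 the effect rose by 1.10. Mean changes of lists were 2.54 for the Hoxb cluster, 1.60 for endoderm, 1.33 for the Hoxa cluster, 0.93 for retinoic acid targets, 0.53 for neural (6 of 18 members tested), 0.49 for the Hoxc and Hoxd clusters and 0.38 for trophoblast. They were -0.58 for formative and primed pluripotency and -0.33 for general pluripotency. The trophoblast call was lost with an estimated correlation (adjusted p = 0.203), and both it and the Hoxc and Hoxd call were lost after quantile normalization (adjusted p = 0.131 and 0.0722) and with FPKM (adjusted p = 0.0711 and 0.0861).

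For other splits, time and the RA effect shared by both times were taken out, RA was reassigned within each time, and both were added back. Of 100 such assignments only 1, the real one, called as many as 955 genes, and the highest other called 1. A chance assignment among these libraries is thus an unlikely source of that count. Chance between cultures cannot be excluded, because the replicates may not be separate cultures. A first form written before reassigned RA without that step. It asks whether RA had an effect at either time, not whether its effect changed, so it is not used here, and in it 3 of 100 assignments called 955 genes or more, with at most 1842.

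Libraries of 1 group differed along a shared axis that held 67.2% of the variance within groups in the time course and 70.1% in the Cyp26a1 set. Gene loadings of the axes from both sets correlated with r = 0.889 over 12119 genes. GC content is a candidate explanation, as loadings correlated with it at rho = -0.61 in the Cyp26a1 set and -0.70 in the time course, and with exonic length at 0.40 and 0.32. Sequencing depth could not be told from no relation, with r = -0.31 over 15 libraries (permutation p = 0.439). A differentiation state that differs between cultures was not decided either, because the squared loadings of developmental list genes were 0.723 of those of all genes (95% bootstrap interval 0.41 to 1.10, added after the ratio was seen).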

How the results depend on the processing

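Of 8515 values for 468 results of named genes, 8092 kept direction and call whatever their size, 392 lost the call and 15 gained it. Another 16 turned direction without a call in either setting, and 0 turned direction with a call. Among all tested genes, 1 called gene turned direction with RA at 24 h and 1 at 24 h without RA, both after correction for GC content and length. The knockout comparison held 158 of the lost calls and the change of the RA effect 92. Of 1671 values for gene lists 1551 kept direction and call, 50 lost the call, 16 gained it and 54 turned the sign of a test without a call. An estimated correlation ended 24 list calls. It left 3 lists past the threshold for RA at 12 h in place of 10, 5 without RA at 12 h in place of 8, and 0 in the knockout in place of 7. Replicate number as a block ended 2 list calls. These were general pluripotency with RA at 12 h (adjusted p = 0.0518) and trophoblast at 24 h without RA (adjusted p = 0.0521). In the knockout the block gave 396 higher and 766 lower genes, against 429 and 855, and 336 and 676 of them were shared with the main result. Among named genes it ended the calls of Rdh10, Hoxa5, Sox1, Tfap2a, Mael and Sesn2.

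Counts depended on scaling and on single libraries. For the change of the RA effect, 383 genes were higher with a mean of at least 5 TPM, 385 with median-of-ratios scaling and 279 with quantile normalization. Of 226 values for the 12 counts of genes changed by 2-fold or more, 28 moved by more than 1.5 times. At 24 h with RA, genes lower by 2-fold or more numbered 269 with a mean of at least 5 TPM and 1338 without RA_24h library 2, against 436. At 12 h with RA they numbered 79 with FPKM and 399 without noRA_12h library 2, against 147, and in the knockout 226 with a pseudocount of 0.1, against 107. In the knockout 558 genes were lower with median-of-ratios scaling and 477 with quantile normalization, and 284 were higher with FPKM. Without 1 library, RA at 12 h called 1039 to 1485 genes higher and 710 to 1243 lower, and RA at 24 h 2361 to 3861 and 1305 to 3567. The change of the RA effect ranged from 333 to 1007 higher and 239 to 538 lower, and the knockout from 114 to 982 higher and 179 to 2178 lower.

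The following alternatives were chosen after the data were seen. Correction for GC content and length gave 2049 lower genes with RA at 12 h and 2981 at 24 h, 858 lower for the change of the RA effect and 933 higher in the knockout, or 895 higher with the block as well. With the covariate for the axis within groups, 1882 genes were lower with RA at 12 h. For the change of the RA effect 1742 were higher and 1190 lower, and in the knockout 1281 and 2366. Without noRA_12h library 1 and RA_24h library 2 together, 4109 genes were lower with RA at 24 h and 4407 at 12 h without RA, and for the change of the RA effect 1968 were higher and 2032 lower.

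Among the genes higher with RA at 24 h the median knockout change was -0.126 (camera p = 0.289 with an estimated correlation) and ranged from -0.153 to -0.0924 without 1 library. For the genes higher at 12 h it was -0.0561 and the test pointed the other way (n = 1310 genes, camera p = 0.799). Among the genes lower with RA at 24 h it was 0.0101 (camera p = 0.204 with an estimated correlation), from -0.0240 to 0.0502 without 1 library, and -0.0398 for those lower at 12 h (n = 855 genes, camera p = 0.211). In the time course, libraries with the same number were no more alike than others, as 30 such pairs had correlations from -0.84 to 0.42 with 7 above 0.1.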

Other observations

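Imprinted genes, a class with expression from 1 parental copy, were not among the lists fixed in advance and were looked up after the largest changes had been seen, as were the other groups of this part. Of 24 tested imprinted genes 7 rose with RA at 24 h, 5 fell and 12 were not past the threshold. H19 went from 20.6 to 188 ± 39.1 TPM (3.12, SE 0.14) and Dlk1 rose by 2.84 (SE 0.24), while the maternally expressed RNAs of the Dlk1 region Meg3 and Rian fell by 1.93 (SE 0.15) and 2.56 (SE 0.32). In the knockout 1 of 23 was higher, 5 were lower and 17 were not past. Mest fell from 469 to 196 TPM (-1.26, SE 0.05), and Dlk1 and Phlda2 fell by 0.92 and 1.05.

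Gamma crystallins, lens proteins encoded by similar neighbouring genes whose reads can be shared, had 4 members higher and 1 not past with RA at 24 h, with Crygd at 2.51 and Cryge at 2.29. In the knockout 4 were lower and 2 not past, with Cryge at -1.18 and Crygd at -1.11. Class II MHC genes, which present antigens on immune cells, had 4 higher and 3 not past with RA at 24 h, such as H2-Ab1 (1.36), and 2 lower and 4 not past in the knockout, H2-Ab1 (-1.46) and H2-Eb1 (-1.35). Hprt, used as a housekeeping gene, lay between 0 and 1.14 TPM in the time course and between 0.998 and 1.89 TPM in the Cyp26a1 set.

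For the pattern that follows, the GC correction, the autosome test, the estimated correlation between late and early genes and the form of the endoderm test limited to 10 markers of low baseline were chosen after the result was seen, while the comparison of late and early genes by shuffles was written before. Genes higher with RA at 24 h had a median knockout change of -0.126, with 472 of 2945 called lower and 121 higher, and as a set they did not pass with an estimated correlation (camera p = 0.289). After correction for GC content and length 470 were called lower and 231 higher. The median was then -0.0534 (n = 2924 genes, camera p = 1.02e-04 with the preset correlation). That test was not repeated with an estimated correlation, so it stays open whether such bias accounts for all of the pattern. Gain or loss of a whole autosome in most knockout cells is not the source, with an autosome median of largest size of -0.0736. In a single library it reached -0.193 (chromosome 13, knockout library 1). A gain or loss in few of the cells would not be seen this way.

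A shortfall in the later part of the RA response was not decided. The 483 genes whose RA effect grew had a median knockout change 0.256 below that of 883 genes called at both times without a called change of the effect (-0.256), and -0.270 to -0.229 without 1 library. The one-sided permutation p was 1e-05, the smallest that 100000 shuffles can give, but shuffles take genes as independent. With an estimated correlation between the 1366 genes, camera gave p = 0.0731 (n = 1366 genes), which keeps it open. Late genes also had the larger RA effect at 24 h (median 1.01 against 0.737), though among genes changed by 2-fold or more their median was -0.456 (246 genes) against -0.124 (263 genes). Some of the 883 may have changed by less than the tests can call. The 483 also include genes whose effect grew because the level without RA fell. Between 12 h and 24 h Cdx1 went from 3.66 to 0.691 TPM without RA and from 104 to 97.0 TPM with it. That class is thus not the later response alone. A lower share of 1 endoderm-like cell type would lower all its markers alike only if no other cells given RA express them. Log2 ratios of the 10 markers ran from -2.32 to -0.86 and their SD was 3.88 times the mean standard error. As expression in other cells was not measured and the standard errors may be technical, these ratios do not decide the question. The pattern itself could rest on few libraries, since without knockout library 3 the median was -0.0924 with a camera p of 0.492, though -0.0288 with a camera p of 0.00408 when GC content and length were corrected as well.

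For the other comparisons the 10 splits of 6 libraries are too few to reach a share under 0.05. The real split was 1 of 10 in each, with 2431 genes against at most 1 in another split for RA at 12 h, and 4915 against 0 for RA at 24 h. Without RA the counts were 5922 against 0 at 12 h and 7244 against 0 at 24 h, and for the knockout 1284 against 1. If knockout libraries are paired with wild type libraries by number, only 4 splits part all 3 pairs, and the real one is 1 of those 4.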
